A study of Mus musculus with 6 samples.

How the data were processed

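RNA was measured in 6 libraries of polyadenylated RNA from mouse branchial arches at E11.5. The branchial arches are the paired swellings of the embryo that form the jaws, middle ear and throat. Per the labels, cells were freed with papain, sorted on the red reporter protein TdTomato, which Wnt1-cre switches on in the neural crest, and used for a stranded mRNA library. The 3 DKO (double knockout) libraries carried floxed alleles of both Ehmt1 and Ehmt2, and the 3 control libraries carried unfloxed alleles of both genes together with the same reporter and Wnt1-cre. The labels call the replicates biological and do not say whether a library holds 1 embryo or a pool.

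The deposited table holds whole-number counts per gene symbol, with no normalization. Per the submitters' processing notes, Trim Galore, STAR 2.7.10a and Picard were used with genome build mm10. The counting program, its strand setting, the gene annotation and any removal of duplicate reads are not given in the sources used here, so reads that fall on overlapping genes or on near-identical copies could have been split, shared or dropped. The table lists 21006 symbols, and 3202 of them had no count in any library. All 21006 symbols matched the RefSeq gene table of the same assembly, and 20994 of these genes are protein coding. Mitochondrial genes and X inactivation RNAs were not analysed here, so a mitochondrial share was not computed and the list of X inactivation RNAs had no tested member. Coordinates are those of that RefSeq table, on mm10, counted from 1.

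Total counts lay between 23414466 and 44538260 per library, a ratio of 1.90. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), which left 14555 tested genes, and libraries were scaled by TMM. The main test was the robust quasi-likelihood test of edgeR, 2-sided, with group as the only term. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p below 0.05 with no minimum fold. Log2 fold changes are DKO over control. The standard error of a log2 fold change is its size divided by the root of the F statistic, and levels are TMM-scaled CPM (counts divided by the scaled library total) with the SD over 3 libraries. The common dispersion was 0.0232. On counts simulated for the comparison of DKO with control over 14555 genes, with 200 genes changed, the test called 80 of 100 genes changed 2-fold and 96 of 100 genes changed 4-fold, in the right direction, and 8.81% of its 193 calls were unchanged genes. The changed genes were drawn from those with a mean of at least 1 CPM, so these rates do not cover genes below that level.

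The groups, the tests, 39 gene lists, the rule for named genes and the alternatives to be tried were chosen before the data were examined. The rule names Ehmt1 and Ehmt2. It then takes, among called genes whose groups do not overlap and whose higher group has a mean of at least 1 CPM, the 15 largest rises and the 15 largest falls. It adds the 5 called genes with the smallest adjusted p in each direction. It names up to 4 called members of each list by adjusted p, or, where no member was called, up to 2 members with the highest mean level. Symbols made of Gm and digits, symbols ending in Rik, and clone identifiers were left out, and genes of the 2 sex-linked lists were not named as results. Genes named outside this rule are marked as chosen after their values were seen.

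The lists cover H3K9 methylation, germline, 2-cell embryo, imprinted, clustered protocadherin and REST target genes. They cover the patterning and fate of crest (distal arch, proximal arch, Hox, early crest, ectomesenchyme, bone, cartilage, extracellular matrix) and pathways (Hedgehog, BMP, Wnt, FGF, retinoic acid, Notch). They also cover cell states (p53, G2 and mitosis, S phase, interferon, integrated stress response, immediate early, hypoxia and glycolysis) and other cells that a sort could hold (neuron, glia, melanocyte, smooth muscle, epithelium, endothelium, erythroid, immune, muscle and mesoderm, neural tube). The last 2 lists are sex-linked, and the Y-linked one was tested like the others. Each list was tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, 2-sided, adjusted over the 38 lists with a tested gene. It was tested again with the correlation estimated from the data. This second form also reads its statistic on the few degrees of freedom that 6 libraries leave, so its p-values differ by more than the correlation. On 38 simulated lists with 1 changed list, camera called that list and 0 unchanged lists, but simulated genes are independent of one another, which real genes are not. Groups of 3 libraries that mixed DKO and control gave 12 to 22 called lists with the preset correlation. The comparison of DKO with control gave 11, so such a call does not by itself set DKO apart from control.

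Alternatives tried were a replicate block, RLE, upper-quartile and library-size scaling, the DESeq2 1.42.0 Wald test, limma-voom, other filters on low counts, a test against a 1.5-fold change, thinning all libraries to the smallest total, leaving out each library, and, for lists, fry. A fit with a term for the presence of Y-linked counts was added after the data were seen. Library totals, detected genes and marker levels were compared by exact 2-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. Replicates of 1 group differed by far more than sampling noise (chi-square per degree of freedom 12.1 to 51.0 for pairs of libraries), so no 2 libraries were taken as 1 sample. No outlier test was made, because groups of 3 are too small for it.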

Results

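The libraries profile the transcripts of TdTomato-positive neural crest cells from the branchial arches of 3 DKO and 3 control samples at E11.5. The comparison asks how gene expression in arch neural crest differs when Ehmt1 and Ehmt2, which encode the paired H3K9 mono- and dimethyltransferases GLP and G9a, are floxed in cells that express Wnt1-cre. Total counts were 36486368, 42373739 and 43308962 in DKO replicates 1 to 3, and 44538260, 23414466 and 30385724 in control replicates 1 to 3. Detected genes numbered 16825 ± 145 in DKO and 16192 ± 266 in control libraries (SD, n = 3 each), an exact permutation p of 0.1, which is the smallest that 3 against 3 can give. The 10 most abundant genes took 1.70% ± 0.0677 of counts in DKO and 1.87% ± 0.176 in control libraries (SD, n = 3 each; exact permutation p = 0.3). The Y-linked genes summed to 1 count in DKO replicate 3 and 0 counts in control replicate 2, against 4635 to 8794 counts in the other 4 libraries, so each group held 1 library without Y-linked transcripts. The Y-linked list, with 4 tested members, was not called by camera (adjusted p = 0.972).

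Both targeted genes were lower in every DKO library than in every control library. Ehmt2 (chromosome 17, 34898463 to 34914073) stood at 128 ± 11.3 CPM in DKO and 355 ± 7.13 CPM in control libraries (SD, n = 3 each), a log2 fold change of -1.47 (SE 0.08; edgeR adjusted p = 0.000208). Ehmt1 (chromosome 2, 24790769 to 24919643) stood at 148 ± 18.2 CPM and 259 ± 8.92 CPM (SD, n = 3 each), a log2 fold change of -0.81 (SE 0.10; edgeR adjusted p = 0.00476). By library, Ehmt2 measured 124, 119 and 140.4 CPM in DKO replicates 1 to 3 against 347, 359.7 and 358 CPM in the controls. Ehmt1 measured 144, 133 and 168 CPM against 250.03, 259.7 and 268 CPM. Counts per gene include exons outside a deleted part, so these levels do not measure how much intact transcript was left. Against a 1.5-fold threshold the Ehmt1 call ended (adjusted p = 0.277).

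**Figure D1:**
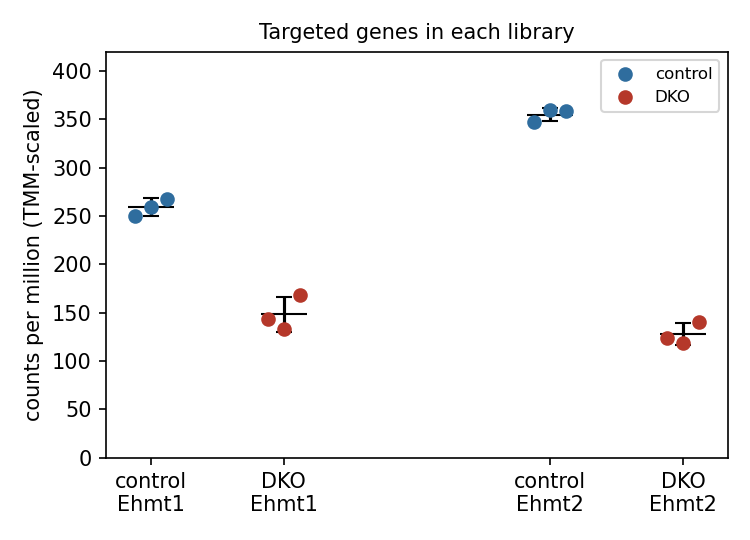
Level of Ehmt1 and Ehmt2 in each library, in TMM-scaled CPM on a linear axis from 0. Points are libraries, and bars give the mean and SD of 3 libraries. All 3 DKO libraries lie below all 3 control libraries for both genes.

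Loss of Ehmt1 and Ehmt2 went with more rises than falls, and called genes in both directions had a lower median level than all tested genes. Of 14555 tested genes, 319 were higher and 119 were lower in DKO, and all 438 separated the 3 DKO from the 3 control libraries without overlap. Such separation was seen for 27.2% of all tested genes, where chance gives 10%. The mean of both groups, a measure chosen after the data were seen, had a median of 3.94 CPM over genes called higher, 10.96 CPM over genes called lower and 31.99 CPM over all tested genes. Of the rises, with a median log2 fold change of 1.52, 133 had a control mean under 1 CPM, and of the falls, with a median of -1.003, 27 had a DKO mean under 1 CPM. A low level in the lower group is partly fixed by the change itself and by the filter. At least 2-fold changes made up 218 of the rises and 60 of the falls. Among genes with a control mean of at least 10 CPM the counts were 98 higher and 72 lower. Scaling by library size only moved the split from 319 higher and 119 lower (72.8% higher) to 416 and 80 (83.9% higher). The excess of rises was small with the DESeq2 Wald test (624 and 482, 56.4% higher) and without DKO replicate 3 (597 and 509, 54.0% higher). Without any other 1 library the share lay between 71.1% and 84.0%.

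These counts changed when any 1 library was left out. Such a fit has fewer libraries and less power, so a lost call does not by itself mark dependence on that library. Each of the 438 called genes kept its sign in every such fit that tested it. Without DKO replicate 1, 2 or 3 the calls were 110 higher and 21 lower, 187 and 59, and 597 and 509; without control replicate 1, 2 or 3 they were 120 and 35, 138 and 32, and 140 and 57. The call held without each of the 6 libraries in turn for 110 genes, 92 higher and 18 lower. Of the 68 called genes named here under the fixed rule, these were Abcc2, Akr1c13, Akr1cl, Aldh1a7, Ehd2, Ehmt1, Ehmt2, Fam163b, Kcnj16, Meioc, Myl1, Mylk3, Neb, Nxf3, Otol1, Pcdhb19, Pcdhga1, Pcdhga2, Pcdhga3, Pcdhga5, Prg4, Rhox5, Slc5a4b, Slc7a11, Tcfl5, Tcp11x2, Tie1, Tmco5b and Unc5cl, and the others lost the call without at least 1 library. Other alternatives ended the calls of Actg2, Aldh1a1, Bmpr1a, Fosb, Ifi27, Il3ra, Myh6, Pcdhb8, Pcdhb21, Tnni1 and Tyr (edgeR, or limma-voom for Ifi27, and both for Actg2 and Pcdhb8; adjusted p between 0.051 and 0.11), and the test against a 1.5-fold change ended 33. On the first principal component of the log2 levels, which held 46.6% of the variance, DKO replicate 3 lay nearest the controls (-12.3, against -31.8 and -37.0 for the other DKO libraries and 19.1 to 31.2 for the controls).

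**Figure D2:**
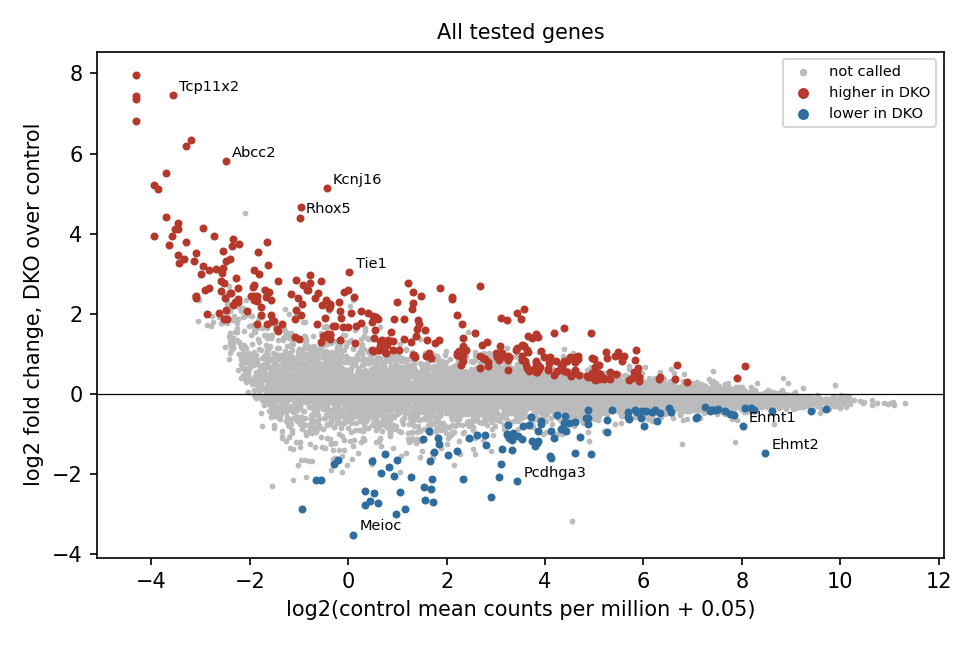
Log2 fold change of DKO over control for each of the 14555 tested genes against log2 of the control mean (CPM + 0.05). Red points are the 319 genes called higher and blue points the 119 called lower by edgeR at an adjusted p below 0.05. The 4 called genes with no count in any control lie at the left edge, where the fitted fold depends on the prior count.

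The largest rises were in genes close to silent in control crest. Kcnj16, an inward-rectifier potassium channel gene, had the smallest p-value of all and rose from 0.687 ± 0.0838 CPM to 24.6 ± 3.92 CPM (SD, n = 3 each), a log2 fold change of 5.13 (SE 0.19; edgeR adjusted p = 3.06e-05; chromosome 11, 110968033 to 111027968). Abcc2, an organic anion transporter gene, rose from 0.128 ± 0.0343 to 7.74 ± 1.83 CPM (log2 fold change 5.82, SE 0.32, adjusted p = 0.000208). The aldo-keto reductase genes Akr1c13 and Akr1cl rose to 6.68 ± 0.522 and 11.4 ± 0.461 CPM, from 0.0596 ± 0.103 and 0.465 ± 0.229 CPM. On the X chromosome, the homeobox gene Rhox5 rose from 0.455 ± 0.182 to 9.24 ± 1.38 CPM (log2 fold change 4.40, SE 0.32, adjusted p = 0.000558), and the RNA export family gene Nxf3 from 0.0523 ± 0.0467 to 4.04 ± 1.33 CPM. Tcp11x2, a testis gene on the same chromosome, had 3 counts over the 3 controls and 769 over the 3 DKO libraries, a ratio of 196 with a 95% counting interval of 67.0 to 954. Slc5a4b had 2 and 141 counts, a ratio of 54.0 (14.7 to 450.4). Both intervals cover counting error only, and leave out the spread between libraries and any duplicate reads.

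The remaining genes among the 15 largest rises to a DKO mean of at least 1 CPM were Tmco5b, Abca16, Otol1, Fam163b, Crtam, Unc5cl and Slc5a8. Their log2 fold changes were 4.15, 3.94, 3.87, 3.79, 3.74, 3.69 and 3.58 in that order. They had 8 (Abca16) to 27 (Fam163b) counts over the controls. With each library left out in turn, Tmco5b ranged from 3.82 to 5.31, Abca16 from 3.31 to 4.57 and Slc5a8 from 3.20 to 4.19. Fam163b lies 2.32 Mb from Ehmt1. Below a DKO mean of 1 CPM, Akr1c12, Toporsl, Ces1a and Cpa1, named after their values were seen, rose by 7.97, 7.43, 5.11 and 4.27. These 4 calls held without each of the 6 libraries. Aldh1a7, a retinaldehyde dehydrogenase relative, and Mylk3, the cardiac myosin light chain kinase gene, were among the 5 rises with the smallest p. Aldh1a7 rose from 4.28 ± 0.387 to 22.1 ± 1.30 CPM (log2 fold change 2.36, SE 0.12, adjusted p = 0.000208), and Mylk3 from 2.74 ± 0.381 to 14.8 ± 1.24 CPM (log2 fold change 2.43, SE 0.16, adjusted p = 0.00049). Akr1c13, Tcp11x2 and Aldh1a7 have close paralogs, so their counts are uncertain to the extent that reads were shared.

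The falls were led by a meiotic regulator and by clustered protocadherins. Meioc, which maintains meiotic prophase in germ cells, fell from 1.03 ± 0.118 to 0.0874 ± 0.0243 CPM (log2 fold change -3.51, SE 0.36, edgeR adjusted p = 0.0023; chromosome 11, 102665351 to 102682240). Tcfl5, a testis transcription factor gene, fell from 2.17 ± 0.27 to 0.29 ± 0.0713 CPM (log2 fold change -2.87, SE 0.29, adjusted p = 0.00225). Il3ra, a cytokine receptor gene, fell by 2.13 on the log2 scale (SE 0.36, adjusted p = 0.0199), and Ehd2, which encodes a caveolar ATPase, fell by 1.10 (SE 0.11, adjusted p = 0.00204). The other 12 of the 15 largest falls were protocadherins, described next.

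Among clustered protocadherins, cell adhesion receptors of neurons encoded in tandem on chromosome 18, genes of the Pcdhb cluster and of the start of the Pcdhg cluster fell. Of 44 tested members, 21 fell, 1 rose and 22 were not called (27 lower and 3 higher when adjusted over the list alone), with a median log2 fold change of -1.41. All 18 tested Pcdhb genes had negative log2 fold changes, and 15 were called. Their summed level was 6.44 ± 1.94 CPM in DKO and 31.9 ± 9.42 CPM in control libraries (SD, n = 3 each). Among Pcdhb genes with a control mean of at least 1 CPM, the largest falls were in Pcdhb6 (log2 fold change -2.99, SE 0.54), Pcdhb16 (-2.73, SE 0.39), Pcdhb22 (-2.68, SE 0.43), Pcdhb18 (-2.67, SE 0.47) and Pcdhb19 (-2.65, SE 0.34), followed by Pcdhb21 (-2.46), Pcdhb3 (-2.44), Pcdhb8 (-2.42) and Pcdhb7 (-2.36). Without control replicate 1, where these 3 genes were most abundant, Pcdhb6, Pcdhb8 and Pcdhb7 fell less (-2.34, -1.76 and -1.87). Below that level, Pcdhb15, named after its value was seen, fell from 0.473 ± 0.179 to 0.063 ± 0.0232 CPM (log2 fold change -2.88, SE 0.50, edgeR adjusted p = 0.0231). The Pcdha class had 5 tested members, with a median log2 fold change of -0.79, and 0 called. Its summed level went the other way, with 14.4 ± 5.39 CPM in DKO and 9.28 ± 1.502 CPM in control libraries, and overlapped between groups.

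Within the Pcdhg cluster the direction depended on the gene, and the sums overlapped between groups: 83.1 ± 15.9 CPM in DKO against 97.6 ± 13.5 CPM in controls for Pcdhga genes, and 63.6 ± 14.9 against 66.1 ± 7.46 CPM for Pcdhgb genes (SD, n = 3 each). Pcdhga3 (chromosome 18, start 37674335) fell from 10.8 ± 1.36 to 2.38 ± 0.0506 CPM (SD, n = 3 each; log2 fold change -2.18, SE 0.16, edgeR adjusted p = 0.000654), Pcdhga2 by 2.58 on the log2 scale (adjusted p = 0.00225), Pcdhga1 by 2.32 (adjusted p = 0.00583) and Pcdhga5 by 1.75 (adjusted p = 0.00394). Pcdhga11 (start 37755773), the 1 member that rose and so named after its value was seen, went 1.91-fold up from 15.7 ± 1.65 CPM (log2 fold change 0.93, SE 0.14, adjusted p = 0.0144). The last genes of the cluster, Pcdhgc3, Pcdhgc4 and Pcdhgc5, had log2 fold changes of 0.10, 0.30 and 0.12 and were not called. Camera called the list lower (adjusted p = 8.31e-23), and adjusted p = 0.592 with an estimated correlation of 0.39 between its genes. Without DKO replicate 1 or control replicate 1 the list had 6 lower members in place of 21, without control replicate 2 it had 12, and without control replicate 3 it had 9. In each of these fits the list had 0 higher members, so the call of Pcdhga11 ended. Without DKO replicate 3 it had 4 higher members. Pcdhg genes share their last exons, and Pcdhb genes are similar in sequence, so counts of single members are uncertain.

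**Figure D3:**
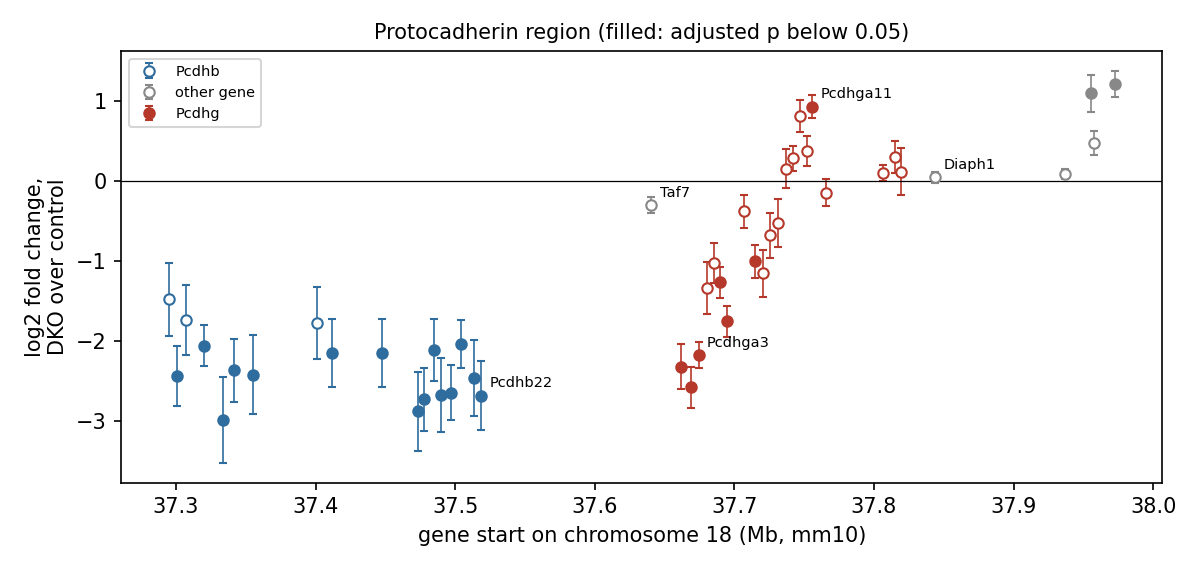
Log2 fold change of DKO over control with its standard error, against gene start on chromosome 18 (Mb, mm10), for tested genes of the Pcdhb and Pcdhg region. Pcdha genes are not shown. Filled points were called by edgeR at an adjusted p below 0.05. Pcdhb genes and the first Pcdhg genes lie below 0, Pcdhga11 lies above 0, and of the neighbours, Taf7 (-0.30) and Diaph1 (0.05) were not called, while Rell2 (1.10) and Arap3 (1.22), named after their values were seen, were called higher. The Rell2 call did not hold when each library was left out in turn.

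Called genes of the germline list went both ways, and few 2-cell embryo or imprinted genes were called, where the share over all tested genes was 3.01%. Of 27 tested germline genes, 2 rose and 2 fell (4 and 7 adjusted over the list alone): Rhox5 and Hormad2 (log2 fold change 2.36, SE 0.40, edgeR adjusted p = 0.0227) were higher, and Meioc and the meiotic cohesin gene Stag3 (-1.13, SE 0.19, adjusted p = 0.0199) were lower. The germline list was not called by camera (adjusted p = 0.587). The list of 2-cell embryo genes had 5 tested members and 0 called (0 over the list alone; camera adjusted p = 0.594), and its most abundant members Duxbl1 and Arg2 had log2 fold changes of 0.62 and -0.20. Of 50 imprinted genes, 2 rose and 0 fell (2 and 1 adjusted over the list alone), namely Ddc (1.02, SE 0.19, adjusted p = 0.0299) and Magel2 (0.38, SE 0.08, adjusted p = 0.0372), and the list was not called (camera adjusted p = 0.525). Without DKO replicate 3 the imprinted list had 3 higher and 3 lower members, and without any other library it had 0.

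Neuronal targets of the repressor REST were higher by camera (adjusted p = 0.00272; adjusted p = 0.988 with an estimated correlation). Of 40 tested members, 3 rose and 0 fell (8 and 0 adjusted over the list alone): the microtubule regulator Stmn3 (log2 fold change 0.71, SE 0.10, edgeR adjusted p = 0.0109), the atypical cadherin Celsr3 (0.86, SE 0.14, adjusted p = 0.0188) and the scaffold gene Mapk8ip2 (1.06, SE 0.18, adjusted p = 0.0284). Without 1 library the REST list had 1 to 7 higher members. The list of H3K9 methylation writers, readers and erasers, which leaves out Ehmt1 and Ehmt2, was lower by camera (adjusted p = 0.00915; adjusted p = 0.977 with an estimated correlation). Of its 36 members, 0 rose and 1 fell (0 and 4 adjusted over the list alone), the demethylase gene Kdm3b (-0.49, SE 0.07, adjusted p = 0.00803). The median of this list was -0.07 and turned to 0.01 with library-size scaling only. The camera call of the REST list ended without control replicate 2 (adjusted p = 0.174) and that of the H3K9 list without DKO replicate 2 (adjusted p = 0.0641).

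Few genes of arch identity were called, but only 3.01% of all tested genes were called, so small counts do not set these lists apart. Of 23 distal arch genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone). It was Hand1, a transcription factor gene of the distal arch, which went from 17.4 ± 1.81 to 9.19 ± 0.47 CPM (SD, n = 3 each; log2 fold change -0.92, SE 0.12, edgeR adjusted p = 0.00776). Camera called the distal list lower (adjusted p = 0.0208; adjusted p = 0.988 with an estimated correlation), a call that ended without DKO replicate 3 (adjusted p = 0.534), control replicate 1 (adjusted p = 0.0512) or control replicate 2 (adjusted p = 0.147). Of 31 BMP genes, 0 rose and 2 fell (0 and 4 adjusted over the list alone), Hand1 and the receptor gene Bmpr1a (-0.35, SE 0.07, adjusted p = 0.0349). The BMP list was lower by camera (adjusted p = 0.00272; adjusted p = 0.988 with an estimated correlation), and not without DKO replicate 3 (adjusted p = 0.159). The 22 proximal arch genes had 0 called (0 over the list alone; camera adjusted p = 0.163), with Nr2f1 at 0.01 and Meis2 at -0.33.

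Of 30 early crest regulators, 0 were called (0 higher and 2 lower over the list alone), with Cdh11 at -0.13 and Twist1 at 0.01. Camera put this list just below its threshold (adjusted p = 0.0499, lower; adjusted p = 0.906 with an estimated correlation), and above it with RLE size factors (adjusted p = 0.0502), with at least 1 CPM in 3 libraries (adjusted p = 0.0532), without DKO replicate 2 (adjusted p = 0.118) or without control replicate 2 (adjusted p = 0.123). Of 35 ectomesenchyme genes, 0 rose and 2 fell (0 and 3 adjusted over the list alone), Foxp2 (log2 fold change -0.61, SE 0.10, edgeR adjusted p = 0.0213) and Fgf10 (-0.72, SE 0.13, adjusted p = 0.0238), and the list was not called (camera adjusted p = 0.176). Fgf10 was also the 1 lower member of the 28 FGF genes (1 higher and 1 lower over the list alone; camera adjusted p = 0.426). Of 26 cartilage genes, 1 rose (1 over the list alone), the lubricin gene Prg4 (2.99, SE 0.32, adjusted p = 0.00312), with camera adjusted p = 0.972. Of 24 retinoic acid genes, 1 rose (2 over the list alone), the retinaldehyde dehydrogenase gene Aldh1a1 (2.33, SE 0.45, adjusted p = 0.0349), with camera adjusted p = 0.988. Aldh1a1 and its paralog Aldh1a7 lie close together on chromosome 19 and had similar log2 fold changes (2.33 and 2.36). Aldh1a1 had means of 0.225 CPM in control and 1.25 CPM in DKO libraries. Its count is uncertain to the extent that reads were shared with Aldh1a7.

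No member was called in the lists for bone, Hox, extracellular matrix, Hedgehog, Wnt or Notch genes. Their tested members numbered 25, 13, 43, 21, 40 and 25, and their camera adjusted p-values were 0.34, 0.315, 0.416, 0.587, 0.0613 and 0.587. Adjusted over the list alone, 3 Wnt genes were lower and the other 5 lists still had 0. The most abundant members had log2 fold changes of 0.22 (Col1a2, bone and matrix), -0.01 (Col3a1, matrix), -0.12 (Ccnd1, Hedgehog and Wnt), 0.06 (Ptch1, Hedgehog), -0.15 (Ctnnb1, Wnt), -0.08 (Notch3) and 0.06 (Notch2). Hoxb3 and Hoxa2, with -0.50 and -0.52, varied between DKO libraries: Hoxb3 stood at 2.10 CPM in DKO replicate 1 and at 25.3 and 42.1 CPM in DKO replicates 2 and 3, against 25.5 to 39.3 CPM in controls.

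Markers of other cell types that a TdTomato sort of arch tissue could hold moved in different directions. Of 42 neuron genes, 0 rose and 2 fell (0 and 4 adjusted over the list alone), the sensory neuron transcription factor genes Tlx3 (log2 fold change -0.61, SE 0.11, edgeR adjusted p = 0.0247) and Pou4f1 (-0.45, SE 0.09, adjusted p = 0.0306). Camera called the neuron list lower (adjusted p = 0.000351; adjusted p = 0.977 with an estimated correlation), and 38 of the 42 members had negative values. Without DKO replicate 3 the neuron list had 9 lower members, and without any other library it had 0. Of 23 endothelium genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), the receptor genes Tie1 (0.965 ± 0.146 to 8.05 ± 0.889 CPM; 3.04, SE 0.20, adjusted p = 0.000503) and Flt4 (1.78, SE 0.25, adjusted p = 0.0099). The endothelium list was higher by camera (adjusted p = 0.0013; adjusted p = 0.592 with an estimated correlation), and without control replicate 1 the list had 1 called member. The mean log2(CPM + 0.5) of its members was 1.72 ± 0.0944 in DKO and 1.35 ± 0.119 in control libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), with no overlap; that of the neuron list was 4.56 ± 0.181 and 4.85 ± 0.179 (p = 0.2).

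Of 26 muscle and mesoderm genes, 5 rose and 0 fell (7 and 1 adjusted over the list alone). Those with the smallest p were the sarcomere genes Myl1 (log2 fold change 3.53, SE 0.39, edgeR adjusted p = 0.00353), Neb (2.30, SE 0.29, adjusted p = 0.00621), Tnni1 (1.63, SE 0.29, adjusted p = 0.0242) and Myh6 (1.76, SE 0.34, adjusted p = 0.0344). All 4 had control means under 1 CPM. Camera called the list higher (adjusted p = 0.0013), and not when genes needed at least 1 CPM in 3 libraries (adjusted p = 0.355). The estimated correlation was 0.0129 and so near the preset 0.01, yet the unadjusted camera p went from 0.000136 to 0.0207 (adjusted p = 0.592). The correlation alone therefore does not account for that change. The estimated form also uses fewer degrees of freedom. Without DKO replicate 1 or 2, or without any 1 of the controls, 2 members were called higher, and without DKO replicate 3 there were 6 higher and 2 lower. The mean log2(CPM + 0.5) of the list was 1.68 ± 0.0922 in DKO and 1.31 ± 0.051 in control libraries (SD, n = 3 each; exact permutation p = 0.1), with no overlap.

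The other cell type lists were not called, and the exact permutation p of their mean levels lay between 0.3 and 1. Single members rose in the lists for glia (L1cam, log2 fold change 0.64, SE 0.10, edgeR adjusted p = 0.0148, 1 of 23), melanocytes (Tyr, 1.70, SE 0.34, adjusted p = 0.0392, 1 of 13), smooth muscle (Actg2, 2.21, SE 0.46, adjusted p = 0.0448, 1 of 22) and red cells (Epor, 1.55, SE 0.25, adjusted p = 0.0165, 1 of 17). Adjusted over the list alone, each of these lists had 1 higher member, and the glia and red cell lists also had 1 lower. Their camera adjusted p-values were 0.972, 0.972, 0.103 and 0.587. Epithelium, immune and neural tube genes had 0 called of 32, 13 and 35 (0 over the list alone; camera adjusted p = 0.859, 0.972 and 0.426). Their most abundant members were Nkx2-1 (0.38) and Spint2 (-0.15), Coro1a (0.11) and Cd68 (0.30), and Nes (-0.18) and Irx3 (-0.10). Haemoglobin genes took 0.00195% of counts in DKO replicate 1 and 0.0329% in DKO replicate 3, with the other libraries between.

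Few genes of the cell state lists were called, where the share over all tested genes was 3.01%. The G2 and mitosis list had 0 called of 46 (0 over the list alone), with Top2a at -0.28 and Mki67 at -0.18, and a median log2 fold change of -0.09, with 38 of the 46 negative. With library-size scaling only, the median was -0.0048 and 24 were negative. Camera called it lower (adjusted p = 0.00482; adjusted p = 0.988 with an estimated correlation), and not without DKO replicate 2 (adjusted p = 0.118) or control replicate 2 (adjusted p = 0.0846). Of 38 immediate early and heat shock genes, which cell dissociation raises, 2 rose and 0 fell (3 and 0 adjusted over the list alone), Ier5 (log2 fold change 0.59, SE 0.08, edgeR adjusted p = 0.00941) and Fosb (0.73, SE 0.15, adjusted p = 0.049). That list was higher by camera (adjusted p = 0.00915; adjusted p = 0.988 with an estimated correlation), and not without DKO replicate 1 (adjusted p = 0.0681) or control replicate 1 (adjusted p = 0.314).

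Of 30 interferon genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.859), and without 1 library 0 to 3 rose and 0 to 1 fell. Ifit2 rose from 18.6 ± 1.94 to 32.7 ± 2.68 CPM (SD, n = 3 each; log2 fold change 0.81, SE 0.11, edgeR adjusted p = 0.00876) and Ifi27 by 2.71 (SE 0.47, adjusted p = 0.024). Oas3 had 3 counts over the controls and 76 over the DKO libraries, a ratio of 19.4 with a 95% counting interval of 6.39 to 96.2. That interval covers counting error only, and leaves out the spread between libraries and any duplicate reads. The median of the interferon list was -0.13 and its mean 0.03. Of 33 integrated stress response genes, 1 rose (1 over the list alone), the cystine transporter gene Slc7a11 (0.95, SE 0.12, adjusted p = 0.00663), with camera adjusted p = 0.972. The p53, S phase, and hypoxia and glycolysis lists had 0 called of 42, 48 and 37 (0 over the list alone; camera adjusted p = 0.988, 0.176 and 0.0613), with Sulf2 at -0.17, Plk2 at 0.12, Rrm1 at -0.27, Uhrf1 at -0.14, Pkm at -0.12 and Eno1 at -0.21.

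Across the 38 tested lists, camera called 4 higher and 7 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.592 and 3 lists had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move one way on balance, called 0 lists (smallest adjusted p = 0.103; 5 lists at an unadjusted p under 0.05). Fry's test for change in either direction called 19 lists. Lists that camera did not call in the main fit became called in some alternatives, all lower but smooth muscle. These were Wnt with the replicate block (adjusted p = 0.0286), with at least 1 CPM in 3 libraries (0.0476) and without DKO replicate 1 (0.0359), DKO replicate 2 (0.00184) or control replicate 3 (0.0123). Hypoxia was called with at least 1 CPM (0.0476) and without DKO replicate 1 (0.00732) or control replicate 1 (3.9e-05), and smooth muscle, higher, with at least 1 CPM (0.0476), the Y-linked term (0.0469) or without DKO replicate 3 (0.0024). Without DKO replicate 1 ectomesenchyme was called (0.0359), without DKO replicate 2 matrix (0.000616), and without DKO replicate 3 Hox (0.0493), neural tube (0.0024) and red cells (0.00124). Without control replicate 1 S phase was called (0.000902), without control replicate 2 neural tube (0.00887), and without control replicate 3 proximal arch (0.023), ectomesenchyme (0.00916), bone (0.0399) and matrix (0.0123). The median, the mean and the camera direction did not share a sign in the cartilage, glia, melanocyte, interferon, integrated stress response, p53 and retinoic acid lists, none of which was called by camera.

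Counts of called members in the other lists also changed when single libraries were left out, in fits with less power. Without 1 library in turn, higher members numbered 1 to 3 and lower members 1 to 4 in the germline list, and 1 to 2 and 0 to 2 in the cartilage list. Lower members numbered 0 to 4 for H3K9 methylation, 0 to 2 for distal arch, 0 to 3 for BMP, 0 to 3 for ectomesenchyme, 0 to 4 for FGF and 0 to 5 for red cells. Higher members numbered 0 to 5 for immediate early, 0 to 3 for smooth muscle, 0 to 2 for retinoic acid, 1 to 2 for integrated stress response, and 0 to 1 for glia, melanocytes and red cells. Lists with 0 called members in the main fit had at most 3 in 1 direction.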

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

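The fit with a term for Y-linked counts was chosen after seeing the data, and the other alternatives were planned. Ehmt2 stayed lower and called in every alternative, and Ehmt1 in every one but the test against a 1.5-fold change (log2 fold change -0.81, adjusted p = 0.277; range over its alternatives 1.1e-11 to 0.277), which asks for a larger change. Each of the 438 called genes kept its sign in each setting that tested it. The counts stayed within 1.5 times the main ones with RLE, upper-quartile or library-size scaling, limma-voom, no filter, at least 1 CPM in 3 libraries, thinning and the Y-linked term (339 higher and 159 lower, with 395 of the 438 genes shared). They moved to 624 higher and 482 lower with DESeq2 (428 shared; the cause was not tested), to 130 and 45 with at least 5 CPM in 3 libraries, which tests 11293 genes, and to 104 and 18 against a 1.5-fold change. Leaving out 1 library gave 110 to 597 higher and 21 to 509 lower. Of 68 named called genes, 29 kept their call without each of the 6 libraries.

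The replicate block gave 423 genes higher and 196 lower, with 416 of the 438 shared, and 12 called lists. Libraries with the same number had correlations of their deviations from the group means of 0.0508, -0.0259 and 0.356, and not each library correlated best with its own number, so the numbers are not taken to pair the samples.

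Of the 11 lists called by camera with the preset correlation, 0 were called with an estimated correlation and 0 by fry. For the estimated form, the parts due to the correlation and to fewer degrees of freedom were not separated. For fry the cause was not tested. Other settings gave 10 to 12 called lists, and leaving out 1 library 8 to 16.

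Only values not called in the main fit changed sign. Without 1 library in turn, log2 fold changes ranged from -0.121 to 0.112 for Col3a1, -1.25 to 0.041 for Hoxb3, -0.472 to 0.0548 for Nes, -0.0487 to 0.132 for Notch2, -0.0243 to 0.0695 for Nr2f1, -0.273 to 0.0492 for Pkm, -0.0204 to 0.113 for Ptch1 and -0.0732 to 0.147 for Twist1. Twist1 had -0.0070 with the replicate block, -0.0063 with limma-voom and -0.0079 with the Y-linked term. Col3a1 had 0.0275 and 0.0683 with upper-quartile and library-size scaling, and 0.0041 and 0.0096 with at least 1 and 5 CPM.

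The adjusted p-values of uncalled lists that changed sign without 1 library ranged from 0.651 to 0.978 for cartilage, 0.000616 to 0.988 for matrix, 0.00916 to 0.978 for ectomesenchyme, 0.142 to 0.95 for epithelium, 0.00124 to 0.894 for red cells, 0.339 to 0.787 for germline, 0.716 to 0.978 for glia, 0.0985 to 0.988 for immune, 0.174 to 0.988 for interferon, 0.448 to 0.956 for integrated stress response, 0.483 to 0.923 for melanocyte, 0.0024 to 0.783 for neural tube, 0.0839 to 0.972 for Notch, 0.0399 to 0.988 for bone, 0.854 to 0.988 for p53, 0.0493 to 0.783 for Hox, 0.651 to 0.988 for retinoic acid and 0.236 to 0.894 for Y-linked genes. With the Y-linked term, the sign changed at adjusted p = 0.991 for the cartilage, immune, p53 and retinoic acid lists. It changed at adjusted p = 0.976 with the replicate block (glia, immune and p53), at 0.963 with fry (p53 and retinoic acid), and at 0.993 (epithelium and retinoic acid) and 0.882 (immune) with at least 1 CPM. The depth of 23414466 to 44538260 counts limits genes near 0 most: of the 133 rises from under 1 CPM, 97 were still called at the smallest total.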

Other observations

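The odds of being called near the targeted loci, the neuron, muscle and endothelium tests, the sum over Pcdhg genes, the neighbour and zinc-finger counts and the genes named in this part were chosen only after their results were seen. Several rises that held without each of the 6 libraries lay in genes outside the fixed lists. Arc, an immediate early gene of neurons, rose from 6.37 ± 1.29 to 41.0 ± 8.24 CPM (SD, n = 3 each; log2 fold change 2.69, edgeR adjusted p = 0.000729). The DNA sensor gene Aim2 rose from 3.604 ± 1.45 to 22.5 ± 0.585 CPM, Cd34, a surface marker of blood and vessel progenitors, from 10.7 ± 2.39 to 44.2 ± 9.13 CPM, the cytokine receptor gene Il2rg from 0.721 ± 0.0857 to 3.45 ± 0.181 CPM, and the collagen gene Col5a3 from 2.43 ± 0.0809 to 14.2 ± 2.85 CPM. The channel genes Scn8a and Cacna1b, expressed in neurons, rose by log2 fold changes of 0.91 and 0.80 (adjusted p = 0.00577 and 0.00857). Single meiotic genes, picked by their values, went both ways. Syce2 went from 24.4 ± 5.25 to 8.74 ± 1.35 CPM (log2 fold change -1.48, edgeR adjusted p = 0.00654), beside the falls of Meioc and Stag3. Hormad2 and Psma8 rose by log2 fold changes of 2.36 and 2.07. The calls of Stag3 and Hormad2 did not hold without each of the 6 libraries. These genes were not tested as a group.

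Of 372 tested zinc-finger genes with a Zfp symbol, a group picked because falls were seen in it, 14 were lower and 1 was higher, against 105 lower among 14183 other genes. No p-value is given, since tandem neighbours do not vary independently. Only 2 of the 14, Zfp110 and Zfp935, kept their call without each of the 6 libraries, and 12 lost it without at least 1. Examples were Zfp935 and Zfp934, neighbours on chromosome 13 (log2 fold changes -1.54 and -1.40), and Zfp975, Zfp976 and Zfp977, neighbours on chromosome 7 (-1.11, -1.38 and -1.65). These genes come in tandem copies, so reads shared between copies leave single members uncertain. Of the 119 genes called lower, 38 had another within 200 kb, against a mean of 5.58 and a highest of 19 in 1000 random draws of as many tested genes. Without the clustered protocadherins it was 17 of 98, against a mean of 3.86 and a highest of 16. For the 319 genes called higher it was 63, against a mean of 38.4 and a highest of 68.

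The first pattern is the fall of clustered protocadherins, whose 21 lower members had a median log2 fold change of -2.36 and start between 37300799 and 37714834 on chromosome 18. Reads moved between Pcdhb genes would leave their sum in place, but it changed by -2.31 on the log2 scale with no overlap between groups; for the 6 lower Pcdhg genes sharing stays open, since together they changed by -31.5 CPM while the sum over all Pcdhg genes changed by -0.0111 on the log2 scale, with a 95% interval of -115 to 109.6 CPM that covers both no change and that fall. Genomic DNA in control libraries would lower other single-exon genes at the level of the Pcdhb genes, and 62 such genes had a median of 0.0020 (95% bootstrap interval -0.098 to 0.21). A smaller share of neurons would lower neuron genes alike. The neuron list had a median of -0.32 (-0.40 to -0.19), with Tlx3 and Pou4f1 at -0.61 and -0.45. However, all 42 members reached 1 CPM in controls and 8 belong to another list. The mean level of the neuron list overlapped between groups (exact permutation p = 0.2). The bootstrap intervals of the single-exon and neuron medians resample genes, not libraries. They leave out the spread between libraries and the correlation between genes. An effect of EHMT1 and EHMT2 loss and a strain difference on chromosome 18 were not tested, and both stay open.

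The second pattern is the rise of 133 genes with a control mean under 1 CPM. Thinning all libraries to the smallest total keeps the expected ratio between groups, so it asks only whether the calls need the greater depth. After thinning, 118 of the 133 genes were still tested, with a median log2 fold change of 2.58, and 97 (72.9% of the 133) were still called. The deepest library was control replicate 1 (44538260 counts), and totals had an exact permutation p of 0.4. Endothelial cells in the sort would bring their abundant transcripts. The endothelium list had a median of 0.37 (0.22 to 0.54), and 0.54 (0.34 to 0.78) over its 9 members under 1 CPM in controls. The intervals of list medians in this paragraph resample genes, not libraries, and leave out the spread between libraries. Egfl7 and Kdr, at 7.93 and 5.75 CPM in controls, had log2 fold changes of 0.12 and 0.25, although 20 of the 23 tested members were positive, Tie1 and Flt4 rose by 3.04 and 1.78, Cd34 outside the list rose by 2.03, and 14 members reached 1 CPM in control crest, so a small rise in that share stays open. A complete TdTomato sort would remove endothelium. For muscle the whole list had a median of 0.49 (0.10 to 0.77), but its 14 members under 1 CPM had 1.04 (0.42 to 1.63), with Des at 7.53 CPM in controls and 0.86 and Myog at 0.42, and 12 of the 26 tested members reached 1 CPM in controls, so muscle cells cannot be told apart from a rise within crest cells for those genes, although a TdTomato sort would remove mesoderm. Of the 133 genes, 6 belong to these 2 lists. The muscle and endothelium lists have only 14 and 9 members under 1 CPM in controls. This count therefore cannot say how many of the 133 rises such cells explain. The mean levels of both lists separated the groups, and a loss of silencing in crest cells was not tested and stays open.

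The third pattern is the set of called genes near the targeted loci. Within 10 Mb of Ehmt1 or Ehmt2, 18 of 503 other tested genes were called (3.58%, 15 higher and 3 lower), against 2.98% elsewhere. They include Cacna1b, Entpd2 and Fam163b, 0.187, 0.605 and 2.32 Mb from Ehmt1 (log2 fold changes 0.80, 2.22 and 3.79). Near Ehmt2 they include H2-Eb2 and Vars2, at 0.573 and 0.757 Mb (log2 fold changes 2.89 and 0.83). Fam163b is also among the largest rises named above. DNA of another strain carried along with the floxed alleles could change such genes, and the odds ratio of 1.21 (95% interval 0.704 to 1.96; Fisher's exact p = 0.423, adjusted p = 0.587 over 4 window sizes), with 1.36, 1.26 and 0.862 for windows of 1, 5 and 20 Mb, leaves open both an excess and none. The interval and the p-values count neighbouring genes as independent, which they may not be, so the interval may be too narrow. Strain DNA cannot be told apart from an effect of the knockout for these 18 genes, because every DKO library carries both floxed loci.

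The 6 libraries split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split called 438 genes and 1 of the 10 splits, the real one, gave as many. The highest of the others called 1 gene. Each of the others mixes DKO and control libraries in both groups, so a difference between DKO and control widens the spread within them. Few calls there were likely in any case, and they do not show how many of the 438 are sound. For lists the order was the opposite: the real split gave 11 camera calls with the preset correlation, all 10 splits gave at least as many, and the highest of the others gave 22. DKO replicate 3 showed the changes called without it at 54.4% of their size in the other DKO libraries (median; 89.1% of 1080 genes in the same direction), and the other 5 libraries at 87.7% to 104%. Genes of the Hox list summed to 21.1 CPM in DKO replicate 1 and to 92.6 to 140.3 CPM in the other libraries. Beyond the protocadherins on chromosome 18, Rell2 and Arap3 (starts 37955054 and 37972623) rose by log2 fold changes of 1.10 and 1.22. The call of Arap3 held without each of the 6 libraries, and that of Rell2 did not.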
